A study of Mus musculus with 28 samples.

How the data were processed

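The study measured RNA in the proximal and the distal colon of female C57BL/6J mice with Affymetrix arrays. The authors extracted RNA with Trizol, amplified it with NuGEN Ovation kits and hybridised a biotin label. The deposited values are log2 expression after RMA (background correction, quantile normalization and summary per probe set), and the labels also name Partek 6.5. A deposited table gives the authors' group means in log2 units, their signed fold change of untreated over treated mice, which is a score with no value between -1 and 1, and their p-value and step-up adjusted p-value for 4 comparisons. The value table held 45101 probe sets in 28 arrays. The largest difference between a deposited group mean and the mean of the deposited columns was 0.0051 log2 units.

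The values of the 6 early arrays carried more decimals than those of the other 22 arrays and look like means of 2 values each. The labels do not say how they were made, so each was used as 1 array. If they are averages, their spread is that of averages. All early arrays and no others have this trait. Where early arrays are compared with others, its effect cannot be told apart from that of the early state.

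Gene names came from the authors' table, which lists 26933 of the probe sets. A mouse symbol matched for 19900 probe sets and a synonym held by 1 gene for 1619, and 2314 kept the name given there. Probe sets listed with several genes (380), without a name (2720) or outside that table (18104), and the 64 controls, were left out of the tests by gene. The median level was 7.942 log2 units in the table and 4.109 outside it. Of the 14123 genes, 5857 had more than 1 probe set, and the probe set with the highest mean over all arrays stood for the gene. Some probe sets may read near-identical genes, so the names Reg3g, Saa1, Cxcl2, Ighm, Sirpb1a, Mcpt1 and Mcpt2 are uncertain to that extent. The table calls Acod1 IRG1, Tmem35a TMEM35, Cxcl5 CXCL6, Slc51a OSTalpha, Ugt2b5 UGT2B17 and Smim38 1810010D01Rik. CYP2C18 is a name of the table for which no mouse gene was found.

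The tests were run with limma 3.58.1 in R 4.3.3. A single linear model of 6 group means was fitted to all 28 arrays, without covariates, with moderated variances (22 residual and 3.78 prior degrees of freedom). A gene was called at an adjusted p under 0.05 by Benjamini and Hochberg over the 14123 genes of a comparison. There were 11 comparisons: the treatment states within each region, the regions within each state, and the difference of the early and of the late response between the regions (interaction terms). SE is the moderated standard error of a log2 difference and SD the spread of the arrays of a group. No further filter on low values was used. The restriction to the authors' table acts like one, since mean levels in it began at 4.115 log2 units and the median outside it was 4.109. List members without a probe set named there were not tested. This left 7 of 15 neutrophil, 13 of 24 inflammatory cytokine and chemokine and 4 of 12 pancreatic acinar genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

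The comparisons, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. In the late and early distal responses, the untreated regions and the late interaction, the rule took the 8 largest rises and the 8 largest falls among called genes, elsewhere the 4 largest of each. Except for the interaction, every array of 1 group had to lie beyond every array of the other, and predicted, Riken, olfactory and unnamed genes were passed over. For the lists, the 3 largest called members or the member with the smallest p were taken, and any member may be named where its list is discussed. Some of these results are not reported here.

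The 24 gene lists were Wnt target genes, cell cycle, inflammatory cytokines and chemokines, epithelial defence, interferon response, extracellular matrix and its remodelling, absorptive colonocyte, goblet cell, enteroendocrine cell, anterior and central Hox genes, posterior Hox genes, B and plasma cell, T and NK cell, macrophage and monocyte, neutrophil, smooth muscle, enteric neuron and glia, adipocyte, squamous epithelium, pancreatic acinar cell, xenobiotic metabolism, fatty acid oxidation and ketogenesis, wound-associated epithelium, and immediate early and heat shock genes. They share 1 gene. Each list was tested in each comparison with camera at a preset correlation of 0.01, adjusted over the 24 lists. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Of the 264 tests camera called 140, camera with an estimated correlation 12, all of them among the 140, and fry 97, of which 89 were among the 140.

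In simulated data of this design, from each gene's mean and pooled SD with 200 changed genes, limma called 44.8% of 1.5-fold, 80.6% of 2-fold and 97% of 4-fold changes in the late distal comparison, and 23.9%, 76.1% and 98.5% in the late proximal one. For the late interaction these shares were 4.5%, 55.2% and 92.4%. The shares hold for 200 changed genes. Where far more genes change, as in the late distal comparison with 6852 genes called, the limit on the unadjusted p is less strict. The simulated shares do not carry over to such a comparison.

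Array medians lay between 6.608 and 6.799 log2 units, and no 2 of the 378 pairs of arrays were identical (highest correlation over all probe sets 0.9971). Centring each array on its median moved the median change of all genes from -0.038 to -0.144 in the early proximal comparison and from 0.028 to 0.122 between late and early proximal tissue. In the early distal comparison it moved from -0.055 to -0.108. No called list turned its direction with centring. Genome coordinates were not used.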

Results

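RNA levels were measured on arrays in the proximal and the distal colon of female C57BL/6J mice in a model of colitis-associated tumours. The mice received azoxymethane (AOM), a carcinogen that acts on the colon, and then cycles of dextran sulfate sodium (DSS), a polymer that injures the colon lining, in the drinking water. The arrays fell into 6 groups: untreated proximal (n = 6), untreated distal (n = 6), early proximal (n = 3), early distal (n = 3), late proximal (n = 4) and late distal (n = 6). Early mice had gone through 2 DSS cycles and late mice through 4. The labels give day 42 for early and day 120 for late mice. A cycle was 5 days of DSS and 14 days of water, and DSS began 96 hours after AOM. According to the labels the distal colon held dysplasia in early mice and both dysplasia and intramucosal carcinoma in late mice, and the proximal colon held neither. Array medians lay between 6.608 and 6.799 log2 units, and the number of arrays limits the precision. Values are log2 differences with SE, or group means with SD, and adjusted p-values are those of the linear model. Where the lower group lay near 4.109 log2 units, the median of the probe sets outside the authors' table, the size of a difference depends on the background and is uncertain. Among others this holds for Mmp7, Acod1, Cxcl5, Spp1, Fpr2, Notum and Adcy8 in the untreated distal colon, for Hoxd13, Cxcl5 and Fxyd4 in the treated proximal colon and for Slc51a in the treated distal colon. A gene named for the size of its change outside a list had no overlap between the arrays of its 2 groups, except in the comparisons of responses. Untreated arrays 1 to 3 and 4 to 6 differed in cell cycle genes within both regions, for a reason the labels do not give, so some comparisons were also run with each set of 3 per region alone, a choice made after seeing the data.

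The untreated colon was compared between its regions to see what set them apart before treatment. The posterior Hox genes Hoxd13 (5.69 ± 1.28 SE, adjusted p = 0.0076) and Hoxb13 (4.74 ± 1.15, adjusted p = 0.0112), of a family that gives tail-end identity in development, were higher in the distal colon. Among anterior and central Hox genes, Hoxb6 (-2.84 ± 0.71, adjusted p = 0.0133) and Hoxb4 (-1.93 ± 0.43, adjusted p = 0.00718) were lower there. Isg15, a ubiquitin-like protein that interferons induce, stood at 10.44 ± 1.15 (SD, n = 6) in the proximal and 7.65 ± 0.39 (n = 6) in the distal colon, a difference of -2.79 ± 0.48 (adjusted p = 0.00393). The proximal colon also held more of Reg3g, an antibacterial lectin (-6.08 ± 1.18, adjusted p = 0.0046), Slc51a, a subunit of the bile acid exporter (-5.06 ± 1.08, adjusted p = 0.00584), and the gut peptide neurotensin, Nts (-5.05 ± 1.00, adjusted p = 0.00474). The distal colon held more of Scnn1a, a subunit of the epithelial sodium channel (1.21 ± 0.23, adjusted p = 0.0046), Lama3, a laminin chain of the basement membrane (1.33 ± 0.21, adjusted p = 0.00366), and Bmp2, a signalling protein (0.67 ± 0.17, adjusted p = 0.0152). Isg15, Scnn1a, Lama3 and Bmp2 had no overlap between groups that include untreated proximal 1 and distal 3, described below. Genes with the other region's levels in those arrays could not meet that condition. The condition therefore does not pick the clearest markers of the regions here.

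Of the 20 measured interferon response genes 7 were lower in the distal colon (12 adjusted over the list alone; camera adjusted p = 2.65e-06, adjusted p = 0.697 with an estimated correlation). The mean of this list was 0.153 to 0.7 in untreated proximal 2, 3 and 4 and -0.871 to -0.549 in untreated proximal 1, 5 and 6. Of the 19 T and NK cell genes 7 were lower, among them Gzma, a granule protease of killer cells, at -3.37 ± 0.62 (9 adjusted over the list alone; camera adjusted p = 4.92e-05, adjusted p = 0.83 with an estimated correlation). Fatty acid oxidation and ketogenesis had 6 genes lower and 1 higher of 16 (10 adjusted over the list alone; camera adjusted p = 6.53e-05, adjusted p = 0.697 with an estimated correlation). Anterior and central Hox genes had 7 lower and 2 higher of 15 (11 adjusted over the list alone; camera adjusted p = 0.00639, adjusted p = 0.697 with an estimated correlation). Posterior Hox genes had 5 higher and 2 lower of 12 (7 adjusted over the list alone), and camera did not call them (adjusted p = 0.074). In total 1384 genes were called, 603 higher and 781 lower in the distal colon, and 117 genes (0.83%, against 0.216% by chance) had no overlap between the groups. The array labelled untreated proximal 1 had the posterior Hox levels of the distal arrays, and untreated distal 3 those of the proximal arrays. The count was 2461 without untreated proximal 1, 2802 without untreated distal 3 and 3575 without both. It was 721, 773, 748 and 854 without untreated proximal 2, 3, 5 or 6, and 784, 867, 757 and 718 without untreated distal 1, 2, 4 or 5. It was 0 with untreated arrays 1 to 3 alone, which include untreated proximal 1 and distal 3, and 1882 with untreated arrays 4 to 6 alone. Fitted without the treated arrays, limma called a single gene between the groups as labelled, Scnn1a (1.21 ± 0.15, adjusted p = 0.0217). That fit keeps untreated proximal 1 and distal 3, which widen the spread of genes that differ between the regions. It therefore does not show how many genes differ between the regions.

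**Figure D1:**
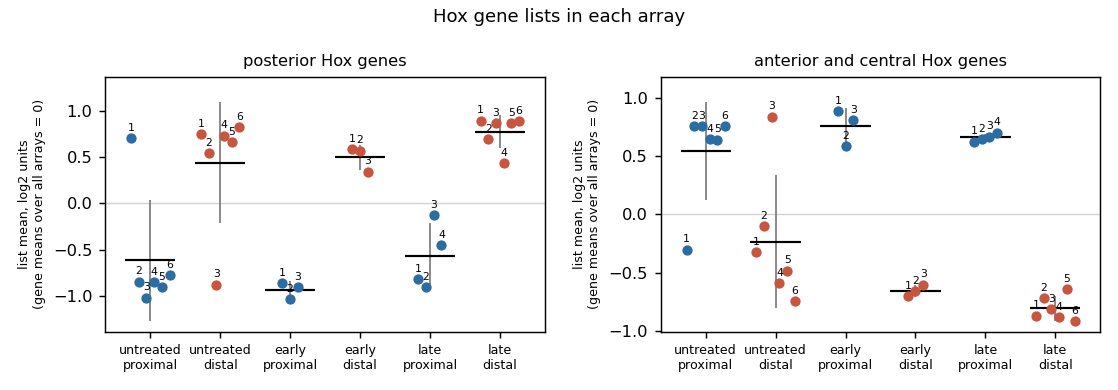
Mean of the posterior and of the anterior and central Hox genes in each array, in log2 units around each gene's mean over all 28 arrays, by group; points are arrays with their replicate number, black lines group means and grey lines ± SD. The posterior mean of untreated proximal 1 (0.71) lay with the distal arrays and that of untreated distal 3 (-0.88) with the proximal arrays.

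The early distal colon was compared with the untreated distal colon to see what changed after 2 DSS cycles. Neutrophil genes rose together. S100a9 and S100a8, which form the calcium-binding protein calprotectin, rose by 6.96 ± 0.56 SE (adjusted p = 1.14e-08) and 6.91 ± 0.55, and S100a9 went from 5.93 ± 1.14 (SD, n = 6) to 12.88 ± 0.73 (n = 3). Il1b, an inflammatory cytokine, rose by 6.04 ± 0.47 (adjusted p = 1.14e-08), and Acod1, the enzyme that makes itaconate in activated macrophages, by 6.29 ± 0.58 (adjusted p = 1.39e-07). Fpr2, a receptor for formyl peptides on phagocytes, rose by 4.64 ± 0.62 (adjusted p = 3.05e-05) and Ighm, the heavy chain of immunoglobulin M, by 5.16 ± 1.21 (adjusted p = 0.0052). Among the genes that fell were Dpyd, the enzyme that degrades pyrimidines (-2.22 ± 0.41, adjusted p = 0.000771), Nmu, the neuropeptide neuromedin U (-2.44 ± 0.46, adjusted p = 0.000859), and Tppp, a tubulin-binding protein (-2.35 ± 0.28, adjusted p = 6.62e-06).

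All 7 neutrophil genes rose in the early distal colon (7 adjusted over the list alone; camera adjusted p = 2.97e-16). Of the inflammatory cytokines and chemokines 12 of 13 rose, among them the neutrophil chemokine Cxcl2 by 2.99 (12 adjusted over the list alone; camera adjusted p = 3.4e-16), and of epithelial defence 5 of 13, among them Lcn2, which binds bacterial siderophores, by 3.78 (5 adjusted over the list alone; camera adjusted p = 1.21e-06). These 3 lists were also called with an estimated correlation. Matrix genes rose in 18 of 23 cases, with the metalloproteinases Mmp10 at 4.15 and Mmp3 at 3.73 (20 adjusted over the list alone; camera adjusted p = 2.41e-15, adjusted p = 0.0675 with an estimated correlation). All 15 B and plasma cell genes rose, Mzb1 by 2.87 (15 adjusted over the list alone; camera adjusted p = 6.87e-15, adjusted p = 0.0675 with an estimated correlation). T and NK cell genes rose in 16 of 19 cases, Cd28, a costimulatory receptor, by 2.83 (17 adjusted over the list alone; camera adjusted p = 2.41e-15, adjusted p = 0.0697 with an estimated correlation). Macrophage and monocyte genes rose in 11 of 14 cases, the chemokine receptor Ccr2 by 2.97 (11 adjusted over the list alone; camera adjusted p = 2.51e-11, adjusted p = 0.0697 with an estimated correlation). Interferon response genes rose in 14 of 20 cases (19 adjusted over the list alone; camera adjusted p = 2.29e-14, adjusted p = 0.0697 with an estimated correlation). Smooth muscle genes fell in 7 of 13 cases, with Smtn at -1.03 (10 adjusted over the list alone; camera adjusted p = 1.14e-06, adjusted p = 0.188 with an estimated correlation). Several of these numbers of genes depend on the untreated arrays used. Against untreated arrays 1 to 3 alone 3 T and NK cell, 7 B and plasma cell, 5 interferon response, 13 matrix and 13 macrophage and monocyte genes rose, and against 4 to 6 alone 16, 12, 17, 16 and 6, and camera called these lists in both settings. Early distal 1 stood below early distal 2 and 3 in these lists. Its means were -0.036 against 0.963 and 0.991 for macrophage and monocyte, -0.786 against 0.715 and 1.591 for interferon response, -0.463 against 1.158 and 1.098 for T and NK cell, 0.354 against 2.124 and 1.892 for B and plasma cell and -0.209 against 1.121 and 1.015 for matrix genes. The macrophage and monocyte mean of early distal 1 lay within the -0.242 to 0.027 of untreated distal 4 to 6.

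Wnt target genes went both ways in the early distal colon. Mmp7 rose by 3.84 ± 0.77 (adjusted p = 0.00146), the receptor Tnfrsf19 fell by 1.34 ± 0.27 (adjusted p = 0.00134), and 1 more of the 22 fell (3 adjusted over the list alone; camera adjusted p = 0.745). The median of this list was -0.003, its mean 0.191 and its camera direction up. None of the 23 cell cycle genes was called by limma (camera adjusted p = 0.854), and their median was -0.322 against untreated arrays 1 to 3 (camera adjusted p = 0.000365) and 0.219 against 4 to 6 (adjusted p = 0.0134). In total limma called 1592 genes, 992 higher and 600 lower, of which 701 rose and 145 fell at least 2-fold. Without overlap were 1435 genes (10.2%, against 2.38% by chance). The count was 900 against untreated arrays 1 to 3 alone (621 higher, 279 lower) and 2682 against 4 to 6 (1234 higher, 1448 lower), and with array weights 2117 were higher and 2937 lower, so which direction holds more genes is not settled. It was 807 without early distal 2 and 509 without early distal 3, and the call of Ighm ended without early distal 3 (adjusted p = 0.065). Early distal 3 was also among the 6 arrays with pancreatic transcripts, and without those arrays, a setting chosen after seeing the data, the count was 363.

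The late distal colon was compared with the untreated distal colon to see what changed after 4 DSS cycles. Wnt target genes rose together, in 21 of 22 cases (22 adjusted over the list alone), with a median of 2.26 log2 units. Mmp7, a matrix metalloproteinase, rose by 8.62 ± 0.63 SE (adjusted p = 7.56e-11), from 4.25 ± 1.15 (SD, n = 6) to 12.87 ± 0.21 (n = 6). Notum, an enzyme that inactivates Wnt proteins, rose by 6.13 ± 0.26 (adjusted p = 3.58e-15), from 4.72 ± 0.15 (SD, n = 6) to 10.85 ± 0.60 (n = 6). Axin2, a feedback inhibitor of the pathway, rose by 1.93 ± 0.16 (adjusted p = 5.12e-10), Lgr5, a receptor of crypt base stem cells, by 2.41 ± 0.31 (adjusted p = 8.38e-07) and the transcription factor Myc by 1.21 ± 0.20 (adjusted p = 3.07e-05). Camera called the list (adjusted p = 2.22e-16), also with an estimated correlation (adjusted p = 0.00851). Wound-associated epithelium rose in 13 of 14 genes, with the tight junction protein Cldn4 at 2.57 and the chaperone Clu at 2.10 (13 adjusted over the list alone; camera adjusted p = 9.73e-07, adjusted p = 0.0267 with an estimated correlation). Cell cycle genes rose in 18 of 23 cases by smaller steps, with the replication helicase subunit Mcm2 at 0.99 ± 0.19 (19 adjusted over the list alone; camera adjusted p = 9.67e-05, adjusted p = 0.275 with an estimated correlation). The mean of this list was -0.105 to 0.343 in untreated distal 1 to 3, -0.534 to -0.401 in untreated distal 4 to 6 and 0.28 to 0.573 in the late distal arrays. Against untreated arrays 1 to 3 alone 5 of the 23 rose (median 0.255, camera adjusted p = 0.0346), and against 4 to 6 alone 20 rose (median 0.85, camera adjusted p = 6.35e-08). The size of the cell cycle rise therefore depends on which untreated arrays are used. Mki67, a marker of dividing cells, was not called (0.31 ± 0.21, adjusted p = 0.241).

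Inflammatory and immune genes were also high in the late distal colon. S100a9 rose by 6.94 ± 0.46 (adjusted p = 1.32e-11), the chemokine Cxcl5 by 6.16 ± 0.68 (adjusted p = 8.83e-08) and the secreted phosphoprotein Spp1 by 6.17 ± 0.59 (adjusted p = 1e-08). Neutrophil genes rose in 6 of 7 cases (6 adjusted over the list alone; camera adjusted p = 1.37e-06, adjusted p = 0.165 with an estimated correlation) and inflammatory cytokines and chemokines in 11 of 13 (12 adjusted over the list alone; camera adjusted p = 3.14e-08, adjusted p = 0.187 with an estimated correlation). Matrix genes rose in 20 of 23 cases, with Mmp10 at 6.16 and Mmp13 at 5.10 (20 adjusted over the list alone; camera adjusted p = 6.79e-09, adjusted p = 0.201 with an estimated correlation). Interferon response genes rose in 17 of 20 cases, with the chemokine Cxcl9 at 5.89 (17 adjusted over the list alone; camera adjusted p = 1.3e-06, adjusted p = 0.249 with an estimated correlation). T and NK cell genes rose in 18 of 19 cases, with the checkpoint receptor Ctla4 at 2.31 (19 adjusted over the list alone; camera adjusted p = 2.36e-06, adjusted p = 0.249 with an estimated correlation), and B and plasma cell genes in 11 of 15 (12 adjusted over the list alone; camera adjusted p = 0.000511, adjusted p = 0.275 with an estimated correlation). Of 14 macrophage and monocyte genes 11 rose, the arginine-degrading enzyme Arg1 by 4.96, and the haemoglobin scavenger receptor Cd163 fell by 3.01 (12 adjusted over the list alone; camera adjusted p = 2.48e-05, adjusted p = 0.249 with an estimated correlation). The mean of this list was -1.289 to -0.851 in untreated distal 1 to 3, -0.242 to 0.027 in untreated distal 4 to 6 and 0.559 to 0.832 in the late distal arrays, and its median change was 1.942 against the first set and 1.049 against the second. Of the 19 T and NK cell genes 10 rose against untreated arrays 1 to 3 alone (median 1.021) and 18 against 4 to 6 (median 1.847), and of the 15 B and plasma cell genes 8 and 7. Epithelial defence genes went both ways, 6 up and 2 down of 13, with Lcn2 at 5.63 (8 adjusted over the list alone; camera adjusted p = 0.0682). Of 10 immediate early and heat shock genes 5 rose, Nr4a1 by 1.09 (5 adjusted over the list alone; camera adjusted p = 0.114).

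Genes of differentiated colon cells fell in the late distal colon. Aqp8, a water channel, fell by 2.90 ± 0.36 (adjusted p = 6.02e-07), from 12.24 ± 0.25 (SD, n = 6) to 9.33 ± 1.27 (n = 6). Trpm6, a magnesium channel, fell by 2.57 ± 0.35 (adjusted p = 2.02e-06), and Slc37a2, a sugar phosphate transporter, changed by -3.64 ± 0.49 (adjusted p = 1.55e-06). Absorptive colonocyte genes fell in 14 of 20 cases, the chloride exchanger Slc26a3 by 1.72 (14 adjusted over the list alone; camera adjusted p = 9.15e-06, adjusted p = 0.201 with an estimated correlation). Goblet cell genes fell in 4 of 11 cases, the transcription factor Atoh1 by 1.04 (2 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.275 with an estimated correlation). Enteroendocrine genes fell in 8 of 14 cases, Tph1, the enzyme of serotonin synthesis, by 1.40 (8 adjusted over the list alone; camera adjusted p = 0.00171, adjusted p = 0.201 with an estimated correlation). Xenobiotic metabolism had 9 genes that fell, Cyp2e1 by 2.04, and 1 that rose, of 10 (10 adjusted over the list alone; camera adjusted p = 4.35e-05, adjusted p = 0.201 with an estimated correlation). Fatty acid oxidation and ketogenesis fell in 11 of 16 genes, the carnitine transferase Cpt1a by 0.98 (12 adjusted over the list alone; camera adjusted p = 6.48e-05, adjusted p = 0.249 with an estimated correlation).

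Genes of the deeper wall fell as well. Smooth muscle genes fell in 11 of 13 cases (11 adjusted over the list alone; camera adjusted p = 6.48e-05, adjusted p = 0.249 with an estimated correlation). Enteric neuron and glia genes fell in 12 of 14 cases (12 adjusted over the list alone; camera adjusted p = 1.14e-05, adjusted p = 0.201 with an estimated correlation). Adipocyte genes fell in 6 of 9 cases, the hormone adiponectin, Adipoq, by 2.00 (6 adjusted over the list alone; camera adjusted p = 0.00461, adjusted p = 0.251 with an estimated correlation). Anterior and central Hox genes fell in 7 of 15 cases (7 adjusted over the list alone; camera adjusted p = 0.00853, adjusted p = 0.249 with an estimated correlation) and posterior Hox genes rose in 2 of 12 (2 adjusted over the list alone; camera adjusted p = 0.414). The anterior and central mean was 0.837 in untreated distal 3, -0.738 to -0.098 in the other untreated distal arrays and -0.909 to -0.638 in the late distal ones, and the posterior mean -0.877, 0.547 to 0.82 and 0.434 to 0.894. Without the 2 untreated arrays with the Hox levels of the other region 8 anterior and central genes fell (camera adjusted p = 0.0164) and the mean change of the posterior genes was 0.074 (camera adjusted p = 0.716). Against untreated arrays 4 to 6 alone camera did not call the anterior and central Hox genes (adjusted p = 0.199), the goblet cell genes (adjusted p = 0.306) or the squamous genes (adjusted p = 0.0529). Squamous epithelium genes rose in 5 of 7 cases, the keratin Krt14 by 3.81 (5 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.275 with an estimated correlation), with list means of 3.54 and 1.76 in late distal 5 and 6 and 0.10 to 0.78 in the other 4 arrays. None of the 4 pancreatic acinar genes was called by limma (camera adjusted p = 0.558), but late distal 2, 3 and 5 held them at 6.30, 4.70 and 2.13 above the median array. In total 6852 genes were called, 3667 higher and 3185 lower, of which 1172 rose and 652 fell at least 2-fold, and with each array centred on its median 3247 were higher (48.2%) and 3483 lower. Without overlap were 3328 genes (23.6%, against 0.216% by chance).

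**Figure D2:**
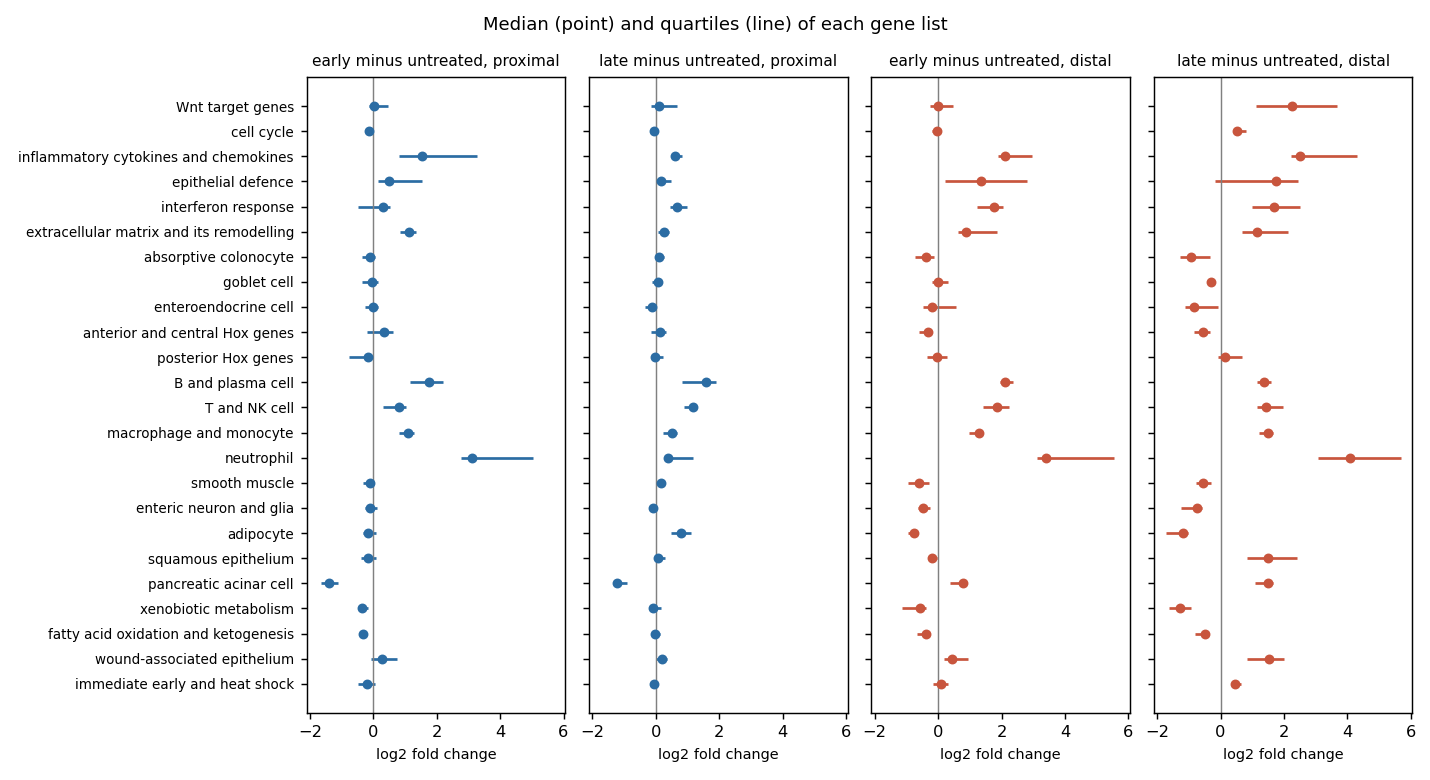
Median log2 difference of the genes of each of the 24 lists in the 4 comparisons with untreated tissue of the same region; lines span the quartiles. The Wnt target genes stood at 2.26 in the late distal colon and at -0.003 in the early distal colon.

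The late and early distal colon, which differ in lesions, DSS cycles and age at sampling, were compared. If the cycles followed each other without a break, they also differ in the time since the last DSS. Their values also differ in decimals, and how the early values were made is not known. Wnt target genes rose in 19 of 22 cases (20 adjusted over the list alone; camera adjusted p = 1.74e-22, adjusted p = 0.00142 with an estimated correlation). Notum rose by 5.81 ± 0.32 (adjusted p = 1.38e-12), from 5.04 ± 0.41 (SD, n = 3) to 10.85 ± 0.60 (n = 6), and the Wnt-induced transcription factor Sp5 by 4.39 ± 0.37 (adjusted p = 3.79e-09). The zinc transporter Slc30a2 rose by 5.28 ± 0.30 (adjusted p = 1.59e-12) and the lectin Itln1 by 5.39 ± 1.10 (adjusted p = 0.00101). Arg1 rose by 2.78 ± 0.38 (adjusted p = 9e-06) while Cd163 fell by 2.43 ± 0.49 (adjusted p = 0.00099). Absorptive colonocyte genes had 8 that fell, Aqp8 by 2.20, and 1 that rose, of 20 (9 adjusted over the list alone; camera adjusted p = 0.000878, adjusted p = 0.525 with an estimated correlation). Enteroendocrine genes fell in 5 of 14 cases, with glucagon, Gcg, at -1.43 (5 adjusted over the list alone; camera adjusted p = 0.000878, adjusted p = 0.304 with an estimated correlation). Cell cycle genes rose in 13 of 23 cases (19 adjusted over the list alone; camera adjusted p = 1.61e-05, adjusted p = 0.525 with an estimated correlation). Of 3398 genes called, 2171 were higher and 1227 lower in the late distal colon. Without early distal 1 the count was 1673, and the calls of the cell cycle genes Cdk1 (1.02, adjusted p = 0.0521 without it) and Mcm2 (1.04, adjusted p = 0.0574 without it) ended.

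The early and late distal responses shared many genes. Of the genes called in both, 835 rose in both and 469 fell in both, where independent lists would share 257.6 and 135.3, and 25 had opposite signs. The correlation of the log2 differences across genes was 0.669, and genes are not independent replicates. Both responses used the same untreated arrays. With unchanged groups and shared controls the simulated correlation averaged 0.344 and ranged from -0.375 to 0.876, so that 0.669 lay inside this range. The covariance was 0.313 against a simulated mean of 0.0185. No gene was called in both in the simulations, but with unchanged groups hardly any call could arise. That count therefore does not show how far shared controls add to the overlap of lists with many calls. With the untreated distal arrays split between the responses the measured correlation was 0.439 to 0.64 over 20 splits.

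The early proximal colon was compared with the untreated proximal colon to see whether the region labelled free of lesions responded. Neutrophil and matrix genes rose there. S100a9 rose by 6.95 ± 0.56 SE (adjusted p = 1.82e-08), from 5.79 ± 0.89 (SD, n = 6) to 12.74 ± 0.53 (n = 3), Mmp3 by 4.80 ± 0.63 (adjusted p = 5.05e-05) and Il1b by 4.34 ± 0.47 (adjusted p = 3.87e-06). Tnni1, a troponin of slow muscle, fell by 2.01 ± 0.34 (adjusted p = 0.000747) and S100g, a calcium-binding protein of absorptive cells, by 2.56 ± 0.54 (adjusted p = 0.00487). All 7 neutrophil genes rose (7 adjusted over the list alone; camera adjusted p = 9.08e-15, adjusted p = 0.0164 with an estimated correlation). Matrix genes rose in 19 of 23 cases, the collagen cross-linking enzyme Lox by 2.70 (20 adjusted over the list alone; camera adjusted p = 2.75e-20, adjusted p = 0.0583 with an estimated correlation). Inflammatory cytokines and chemokines rose in 7 of 13 cases (9 adjusted over the list alone; camera adjusted p = 1.62e-10, adjusted p = 0.0885 with an estimated correlation). Their mean was 2.083 in early proximal 2, -0.102 and 0.393 in early proximal 1 and 3 and -1.335 to -1.035 in the untreated proximal arrays. Macrophage and monocyte genes rose in 9 of 14 cases (13 adjusted over the list alone; camera adjusted p = 7.82e-11, adjusted p = 0.0885 with an estimated correlation). B and plasma cell genes rose in 7 of 15 cases (13 adjusted over the list alone; camera adjusted p = 1.13e-08, adjusted p = 0.205 with an estimated correlation). A single interferon response gene of 20 rose (3 adjusted over the list alone; camera adjusted p = 0.281). Of 1072 genes called, 704 were higher (65.7%) and 368 lower, and with each array centred on its median 572 were higher (40.2%) and 851 lower. Without overlap were 2522 genes (17.9%, against 2.38% by chance). The count was 149 without early proximal 2, which also ended the call of S100g (adjusted p = 0.0573), 616 without early proximal 3, 688 without untreated proximal 5 and 1714 without the 2 untreated arrays with the Hox levels of the other region. It was 285 against untreated arrays 1 to 3 alone and 1738 against 4 to 6, and with array weights 1951 were higher and 1994 lower. Against untreated arrays 1 to 3 alone limma called 0 B and plasma cell, 11 matrix, 7 macrophage and monocyte and 5 inflammatory genes higher, and against 4 to 6 alone 10, 18, 10 and 5, and camera called these 4 lists in both settings.

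Of the genes called in both early responses, 537 rose in both regions and 113 fell in both, where independent lists would share 49.4 and 15.6, and none had opposite signs in the limma calls. The correlation of the log2 differences across genes was 0.78. The early arrays of both regions, and no others, carry the extra decimals. An effect of how these values were made would be shared by both regions. It cannot be told apart from a shared early response. The labels do not say whether arrays of the 2 regions come from the same mice.

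The late proximal colon was compared with the untreated proximal colon in the same way. Limma called 3 genes, all higher. Gpnmb, a glycoprotein of macrophages, stood at 8.73 ± 0.45 (SD, n = 4) against 6.92 ± 0.30 (n = 6), a rise of 1.81 ± 0.25 SE (adjusted p = 0.000647). Cd84, a receptor of leukocytes, rose by 1.19 ± 0.20 (adjusted p = 0.0111), and the uncharacterised 1700007E05Rik, named after its values were seen, by 2.12 ± 0.20 (adjusted p = 5.48e-07). No B and plasma cell gene was called over all genes, 11 of 15 were called adjusted over the list alone, and the median was 1.60 (camera adjusted p = 1.68e-14, adjusted p = 0.163 with an estimated correlation). No T and NK cell gene was called over all genes, 15 of 19 were called adjusted over the list alone, and the median was 1.19 (camera adjusted p = 4.6e-17, adjusted p = 0.163 with an estimated correlation). Late proximal 1 stood at 1.92 for B and plasma cell and 1.96 for T and NK cell genes, in log2 units around the mean over all arrays, and the other 3 late proximal arrays at -0.951 to 0.616 and 0.257 to 0.644. No adipocyte gene was called over all genes or over the list alone, and their median was 0.80 (camera adjusted p = 0.00166, adjusted p = 0.42 with an estimated correlation, adjusted p = 0.254 against untreated arrays 1 to 3 alone). S100a9 differed by 2.03 ± 0.51 without a call (adjusted p = 0.15). At an unadjusted p under 0.05 there were 1193 genes, and 359 had no overlap (2.54%, against 0.952% by chance). The call of Cd84 ended without late proximal 1, 2 or 3 (adjusted p = 0.088, 0.0582 and 0.0828). The count was 16 without untreated proximal 1, 8 without late proximal 4 and 52 without the 2 untreated arrays with the Hox levels of the other region.

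**Figure D3:**
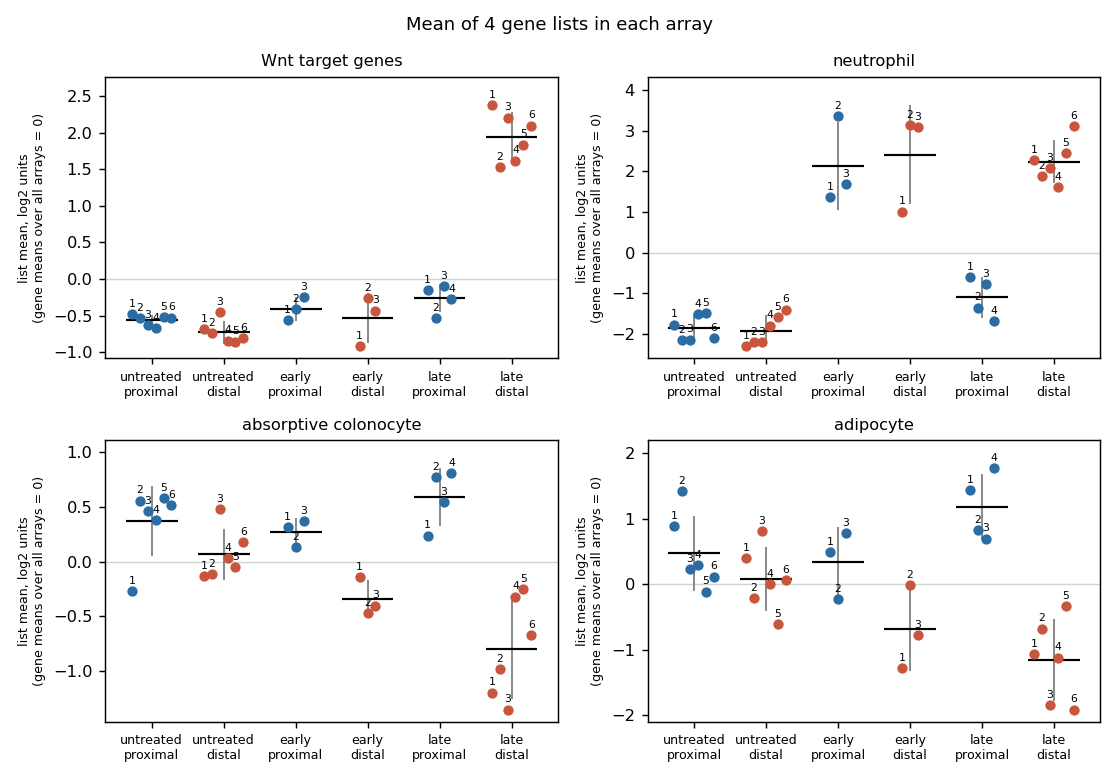
Means of the Wnt target, neutrophil, absorptive colonocyte and adipocyte genes in each array, in log2 units around each gene's mean over all 28 arrays, by group; points are arrays with their replicate number, black lines group means and grey lines ± SD. The Wnt target mean lay at 1.53 to 2.38 in the late distal arrays and at -0.09 or below in all others, and the neutrophil mean at 1.01 to 3.36 in the early arrays and at -1.68 to -0.60 in the late proximal arrays.

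Late and early proximal colon, which differ in DSS cycles and age at sampling, were compared. If the cycles followed each other without a break, they also differ in the time since the last DSS. Their values differ in decimals as well, and the effects of these differences cannot be told apart. Neutrophil genes were lower in late mice in 6 of 7 cases (7 adjusted over the list alone; camera adjusted p = 5.23e-17, adjusted p = 0.00791 with an estimated correlation). S100a9 differed by -4.92 ± 0.61 SE (adjusted p = 0.000106), with 7.82 ± 1.10 (SD, n = 4) against 12.74 ± 0.53 (n = 3), and Il1b by -3.53 ± 0.51 (adjusted p = 0.000561). Matrix genes were lower in 9 of 23 cases (19 adjusted over the list alone; camera adjusted p = 4.03e-19, adjusted p = 0.0483 with an estimated correlation). Inmt, a methyltransferase, was higher by 2.71 ± 0.42 (adjusted p = 0.000984) and the neuronal globin Ngb by 1.63 ± 0.21 (adjusted p = 0.000141). Of 94 genes called, 23 were higher (24.5%) and 71 lower, and with each array centred on its median 39 were higher (43.3%) and 51 lower. The count was 17 and 48 without early proximal 2 or 3, and 301, 25, 41 and 27 without late proximal 1, 2, 3 or 4.

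The regions were compared within early mice. The Hox contrast of the regions was present, with Hoxd13 higher in the distal colon by 7.52 ± 1.81 SE (adjusted p = 0.0295). Atp12a, a proton pump of the distal colon, differed by 6.87 ± 1.46 (adjusted p = 0.0164) and Apoa1, the main protein of high-density lipoprotein, by -6.28 ± 1.17 (adjusted p = 0.00762), with 5.41 ± 0.04 (SD, n = 3) against 11.69 ± 0.43 (n = 3). Anterior and central Hox genes were lower in the distal colon in 9 of 15 cases (12 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.136 with an estimated correlation). Posterior Hox genes had 4 higher and 1 lower of 12 (9 adjusted over the list alone; camera adjusted p = 0.00661, adjusted p = 0.277 with an estimated correlation). Of 268 genes called, 89 were higher and 179 lower, and 2542 had no overlap (18%, against 10% by chance). Without early proximal 3 the calls of Apoa1 (adjusted p = 0.0655), Atp12a (adjusted p = 0.0949) and Hoxd13 (adjusted p = 0.104) ended. The call of Hoxd13 also ended without any other of the 6 arrays (adjusted p from 0.0677 to 0.095), and that of Atp12a without early proximal 1 (adjusted p = 0.0702) or early distal 2 or 3 (adjusted p = 0.073 and 0.0504). The count was 33 and 17 without early proximal 1 or 3, and 26 and 61 without early distal 2 or 3. The SE of these differences pools the spread of all 6 groups, among them the 2 untreated arrays with the Hox levels of the other region. Without those 2 arrays, a setting chosen after seeing the data, the count was 968, and with the early arrays alone it was 433. The lost calls therefore do not measure the spread of the early arrays alone.

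The regions were compared within late mice, where the labels place lesions in the distal colon. Wnt target genes were higher in the distal colon in 20 of 22 cases (21 adjusted over the list alone; camera adjusted p = 4.51e-17, adjusted p = 0.00684 with an estimated correlation). Cxcl5 was higher by 6.22 ± 0.76 SE (adjusted p = 7.79e-07), with 10.60 ± 0.38 (SD, n = 6) against 4.38 ± 1.37 (n = 4), and Fxyd4, a regulator of ion pumps, by 6.63 ± 1.47 (adjusted p = 0.000928). Pnliprp1, a pancreatic lipase relative, was higher by 6.40 ± 1.17 (adjusted p = 0.000126). Slc51a differed by -7.05 ± 1.21 (adjusted p = 6.19e-05). Absorptive colonocyte genes were lower in 16 of 20 cases (16 adjusted over the list alone; camera adjusted p = 9.96e-09, adjusted p = 0.0958 with an estimated correlation), fatty acid oxidation and ketogenesis in 15 of 16 (15 adjusted over the list alone; camera adjusted p = 4e-09, adjusted p = 0.0958 with an estimated correlation). All 9 adipocyte genes were lower (9 adjusted over the list alone; camera adjusted p = 1.92e-06, adjusted p = 0.0958 with an estimated correlation). Of 5208 genes called, 2701 were higher and 2507 lower. After another quantile normalization 2544 were higher and 2616 lower, and with each array centred on its median 2269 (45.7%) and 2700, so which direction holds more genes depends on the scaling. In this comparison 4431 had no overlap (31.4%, against 0.952% by chance).

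The difference between the late responses of the regions was tested as an interaction. Wnt target genes rose more in the distal colon in 21 of 22 cases (22 adjusted over the list alone; camera adjusted p = 8.66e-21, adjusted p = 0.00227 with an estimated correlation), with Mmp7 at 6.47 ± 0.94 SE (adjusted p = 3.7e-05), Lgr5 at 2.84 ± 0.46 (adjusted p = 0.000142) and Axin2 at 1.98 ± 0.23 (adjusted p = 2.38e-06). The mast cell proteases Mcpt2 and Mcpt1 responded more in the distal colon by 6.10 ± 0.79 (adjusted p = 7.63e-06) and 6.09 ± 0.84 (adjusted p = 1.89e-05), and Spp1 by 6.57 ± 0.88 (adjusted p = 1.4e-05). Adcy8, an adenylate cyclase, differed by 5.45 ± 0.48 (adjusted p = 1.46e-08) and Aqp8 by -2.81 ± 0.54 (adjusted p = 0.000856). Neutrophil genes differed in 6 of 7 cases (6 adjusted over the list alone; camera adjusted p = 5.73e-07, adjusted p = 0.133 with an estimated correlation). Absorptive colonocyte genes had lower responses in the distal colon in 12 of 20 cases (14 adjusted over the list alone; camera adjusted p = 6.25e-08, adjusted p = 0.162 with an estimated correlation) and adipocyte genes in 8 of 9 (8 adjusted over the list alone; camera adjusted p = 3.22e-05, adjusted p = 0.162 with an estimated correlation). For B and plasma cell genes limma called none of 15 (0 adjusted over the list alone; camera adjusted p = 0.769, median -0.131, mean 0.009). Of 2739 genes called, 1540 had the higher response in the distal colon and 1199 the lower. Of the 6852 genes called in the late distal colon, 4645 (67.8%) had the same sign in the late proximal colon, where their median change in that direction was 0.081 against a median size of 0.661 in the distal colon.

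For the early responses limma called 0 genes in the interaction, with 501 at an unadjusted p under 0.05. With array weights limma called 375, and 17 without the 2 untreated arrays with the Hox levels of the other region. Isg15 had the largest of the 3 differences with the smallest p, 3.11 ± 0.83 (adjusted p = 0.923). Interferon response genes had a median of 1.36 (0 of 20 called, 4 adjusted over the list alone; camera adjusted p = 2.09e-17, adjusted p = 0.294 with an estimated correlation). The interaction also takes in the difference of the untreated regions, where Isg15 stood at -2.79 ± 0.48 and this list varied among the untreated proximal arrays. Between the regions in early mice the list median was -0.191 without the arrays with pancreatic transcripts (camera adjusted p = 0.741). A stronger early interferon response of the distal colon is therefore not settled.

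**Figure D4:**
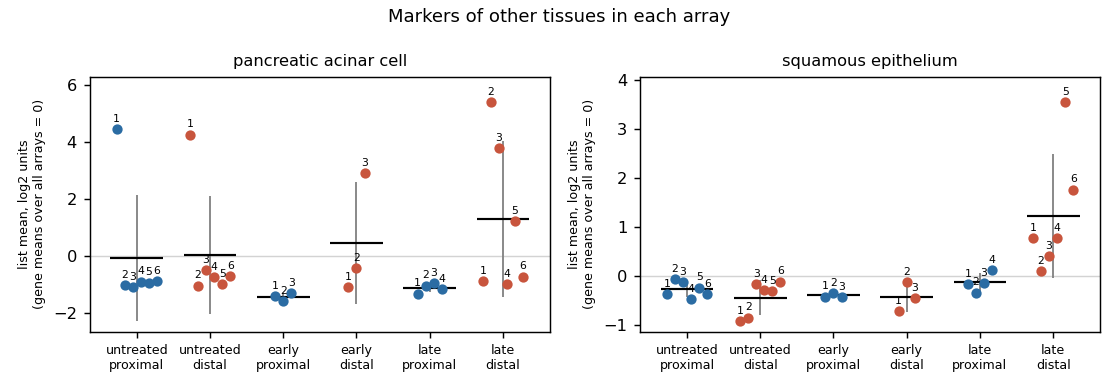
Means of the pancreatic acinar and the squamous epithelium genes in each array, in log2 units around each gene's mean over all 28 arrays, by group; points are arrays with their replicate number, black lines group means and grey lines ± SD. The pancreatic mean was highest in late distal 2 (5.38), and the squamous mean in late distal 5 (3.54).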

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

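In this part the test of AOM/DSS treatment as the source of the pancreatic genes was chosen only after the result was seen.

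The late response differed between the regions in 2739 genes by the interaction test. Among the 21204 probe sets without a single gene name, which the comparisons by gene do not use, 2865 were called between late and untreated distal colon, 1311 higher and 1554 lower.

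Of 96 list means per group that were examined, 12 had a single array far from the others of its group, where chance gives about 1 in 20. Values are log2 distances from the median of the group's other arrays. Untreated proximal 1 stood apart for posterior Hox genes (1.562), anterior and central Hox genes (-1.056), absorptive colonocyte (-0.787), B and plasma cell (1.346), xenobiotic metabolism (-0.612), fatty acid oxidation and ketogenesis (-0.657) and pancreatic acinar genes (5.385). Untreated distal 3 stood apart for posterior Hox genes (-1.61) and epithelial defence (1.539), and untreated distal 1 for pancreatic acinar genes (5.004). Late proximal 2 stood apart for interferon response (0.614), and late proximal 1 for fatty acid oxidation and ketogenesis (-0.362).

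The Hox genes of untreated proximal 1 and untreated distal 3 were those of the other region. On 652 further genes that differed between the regions in the treated arrays, with the other untreated proximal arrays at 0 and the other untreated distal arrays at 1, untreated proximal 1 scored 0.888 and untreated distal 3 scored 0.001, while the other untreated arrays scored -0.04 to 0.075 and 0.902 to 1.041. Tissue of both regions mixed in each array is argued against, since both scores lay at least 0.388 from the middle of the scale. An exchange of the labels of these 2 arrays may account for the pattern, as the scores differed by 0.886 in the direction it needs. Dissection at another site stays open, and no biological explanation was tested.

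Pancreatic secretory genes were high in 6 arrays, by 5.369 in untreated proximal 1, 5.176 in untreated distal 1, 3.814 in early distal 3, and 6.305, 4.701 and 2.129 in late distal 2, 3 and 5, above the median array. AOM/DSS treatment as the whole source is argued against by the 2 untreated arrays among them. Pancreatic tissue carried along in the dissection may account for the signal of the fixed list, since all 6 arrays were also the highest for 10 further pancreatic genes, at 2.918, 2.598, 1.565, 3.686, 2.662 and 1.808 in the same order. The further genes were also at 1.359, 1.27 and 1.531 in late distal 1, 4 and 6, against at most 0.395 in the remaining arrays, so the margin was small for early distal 3 and late distal 5, and a part of their level that goes with the late treatment stays open. Pnliprp1, left out of the further genes before the test because it had been seen to be high there, stood at 12.45 ± 0.52 (SD, n = 6) over the late distal arrays.

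Absorptive colonocyte genes fell in the late distal arrays, with a median of -0.931 and 14 of 20 called lower. Fewer epithelial cells in the tissue was tested with 7 measured genes of all epithelial cells, whose median change was -0.039. This argues against fewer cells only if the level of these genes per epithelial cell stayed the same, which was not measured. The SE of that median, 0.107, comes from the spread across the 7 genes, which are not independent replicates. Their single changes lay between -0.253 ± 0.147 and 0.392 ± 0.135 (moderated SE), with 2 called higher and 0 lower by limma. RNA degradation is argued against because with the 3' to 5' difference of control probe sets as a covariate the median was -1.066 and 15 were called lower. A changed state of the epithelial cells in the treated mice may account for the fall, as an untested hypothesis found on the same data. A change in the mix of epithelial cell types stays open too.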

How the results depend on the processing

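The alternatives that left out the 2 untreated arrays with the other region's Hox levels, the arrays with pancreatic transcripts, untreated arrays 4 to 6 or untreated arrays 1 to 3 were chosen after seeing the data. Of 6900 values of named genes under an alternative other than leaving out 1 array, 6332 kept their direction and their side of the threshold. The call was lost in 424 and gained in 143. Direction turned in 1, Synpo2 between the regions in late mice, at 0.083 with the mean of a gene's probe sets. With 1 array left out, calls were lost in as few as 4 of 287 values (late distal 2) and as many as 50 of 185 (early distal 3). The list interferon response between the regions in early mice turned to -0.191 without the arrays with pancreatic transcripts. Without untreated arrays 4 to 6 the list macrophage and monocyte between the untreated regions turned to -0.385. Without untreated arrays 1 to 3 the list cell cycle turned to 0.219 for early distal and 0.155 for late proximal, and macrophage and monocyte to -0.426 for the early interaction. Leaving out 1 array at a time gave 718 to 2802 genes for the untreated regions, 509 to 2102 for early distal, 6071 to 6943 for late distal, 1673 to 3755 for late against early distal, 149 to 1377 for early proximal, 2 to 16 for late proximal, 17 to 301 for late against early proximal, 17 to 213 for the regions in early mice, 4213 to 5151 for the regions in late mice, 0 to 2 for the early interaction (limma, 501 unadjusted with all arrays) and 2060 to 3011 for the late interaction. With genes above the median level 7061 were tested, so fewer could be called: 530 for early distal, 3514 for late distal, 1979 for late against early distal, 352 for early proximal, 0 for late proximal (limma, 389 unadjusted), 16 for late against early proximal, 106 for the regions in early mice, 2717 in late mice and 1402 for the late interaction. With array weights the counts were 5101 for the untreated regions, 5054 for early distal, 3945 for early proximal, 871 for late proximal, 2644 for late against early proximal, 1596 for the regions in early mice, 375 for the early interaction and 5187 for the late interaction, and the cause was not tested. With only the groups of the comparison the variance came from those arrays alone, and the counts moved both ways. The counts were lower for the untreated regions (1), early distal (851) and late against early proximal (30). They were higher for late proximal (8) and the regions in early mice (433). Without the 2 untreated arrays with the other region's Hox levels they were 3575 for the untreated regions, 1714 for early proximal, 52 for late proximal, 190 for late against early proximal, 968 for the regions in early mice and 17 for the early interaction, and without the arrays with pancreatic transcripts 363 for early distal and 11 for late proximal. Without untreated arrays 4 to 6 they were 0 for the untreated regions (limma), 900 for early distal, 285 for early proximal and 36 for late against early proximal. Without untreated arrays 1 to 3 they were 2682 for early distal, 1738 for early proximal, 61 for late proximal, 210 for late against early proximal, 985 for the regions in early mice and 9 for the early interaction. The authors' deposited p-values, adjusted over the genes tested here, gave 5 for late proximal, 3 higher and 2 lower. The cause was not tested for these. Camera with an estimated correlation called 12 lists in place of 140. Low signal limits the genes near the background, where the arrays cannot show a fall.

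Whether equal replicate numbers in the 2 regions mark the same mouse is not settled. Of 13 pairs 4 correlated at 0.495 to 0.691, and 3 of them were mutually best, while the other 9 lay between -0.233 and 0.093. Among the 4, untreated 1 (0.585) and untreated 3 (0.495) each hold an array with the other region's levels, which may account for their correlation. Both arrays of untreated 1 also held pancreatic transcripts, at 5.369 (proximal) and 5.176 (distal) above the median array. The parts of these traits in its correlation were not separated. Early 1 (0.691) and early 2 (0.55) hold no array of either kind. A random replicate block gave 2167 genes for the untreated regions and 554 for the regions in early mice, and a fixed replicate block 1567 and 368.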

Other observations

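No test in this part was chosen after its result was seen.

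Arrays within a group differed in their inflammatory genes. Neutrophil genes, in log2 units around each gene's mean over all arrays, stood at 1.01 in early distal 1 against 3.14 and 3.09 in early distal 2 and 3, and at 3.36 in early proximal 2 against 1.36 and 1.68 in early proximal 1 and 3. Squamous epithelium genes stood at 3.54 in late distal 5 and 1.76 in late distal 6. Adipocyte genes stood at 0.70 to 1.76 in the late proximal arrays and at -1.91 to -0.33 in the late distal arrays.

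The authors' deposited table lists, at an adjusted p under 0.05, 2261 probe sets for the early distal comparison (1429 higher, 832 lower after treatment), 11995 for the late distal one (5797 and 6198), 1320 for the early proximal one (853 and 467) and 5 for the late proximal one, all higher.

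Other splits of the same arrays were counted for each number of genes called. All were counted where at most 100 were possible, and elsewhere 100 were drawn with the real one among them. The possible splits were 462 for late distal and the untreated regions and 210 for late proximal and the regions in late mice. Chance is argued against where only the real split among those counted gave as many. These were late distal (6852 genes, highest other 3865), late against early distal (3398, highest other 1810), early proximal (1072, highest other 83), the regions in late mice (5208, highest other 2949) and the late interaction (2739, highest other 52). Their shares of 0.01 to 0.012 were the smallest possible. Chance is argued against less firmly where the share was under 0.05 but other splits called more genes. These were the untreated regions (1384, highest other 2379, 4 of 100 splits), early distal (1592, highest other 2300, 2 of 84) and late proximal (3, highest other 9, 3 of 100). Splits that called 2379 or 2300 genes point to a structure of the samples beyond their groups. Chance cannot be excluded for late against early proximal (94, highest other 447, 3 of 35 splits). For the early interaction the real count was 0 by limma, with 501 at an unadjusted p under 0.05, so all 100 splits gave as many whatever the data (highest other 613), and the splits say nothing about it. For the regions in early mice the 10 splits are too few for a share under 0.05 (268, highest other 797, 2 splits as large).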
